A study of Mus musculus with 12 samples.

How the data were processed

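RNA sequencing was done on 12 libraries of splenic conventional dendritic cells from female C57/BL6 mice. Conventional dendritic cells fall into type 1 (cDC1) and type 2 (cDC2). Each subset had 3 libraries from wild-type mice (WT) and 3 from mice whose label gives Zfp366-/- (KO). Zfp366 encodes DC-SCRIPT, a zinc finger protein of dendritic cells. Per the labels, spleens were digested with collagenase and DNAse, and polyA RNA went through a TruSeq preparation. The labels number 6 mouse pools, 3 per genotype, and each pool gave 1 cDC1 and 1 cDC2 library. Groups were taken from the labels alone.

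The authors aligned reads to GRCm38 (mm10) and counted them with featureCounts, per their processing notes, which give no version. The deposited table holds raw read counts per gene, under Entrez Gene identifiers, for 27179 genes. The deposited gene length column is in bases. No normalization had been applied. RefSeq's annotation of GRCm38, the same build, gave symbols and positions for 25275 of the genes, and GENCODE for 18 more. The 1886 genes with neither held 2.22% of the reads.

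Total counts ran from 11330503 in cDC2 WT replicate 3 to 36761685 in cDC2 KO replicate 2, a 3.24-fold range. Levels are in CPM, with library totals scaled by TMM (trimmed mean of M values). Precision follows from this depth and from n = 3: the median standard error of a log2 fold change was 0.33 in either genotype comparison. Where a group had no read, the fold is a lower bound computed from 3 reads over that group. These floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

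One model was fitted to all 12 libraries with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the groups, which left 13415. The fit used TMM scaling, 4 group means and robust quasi-likelihood dispersions. Genes were called at an adjusted p (Benjamini-Hochberg over all genes tested) below 0.05 in the quasi-likelihood F test, and standard errors were the log2 fold change over the square root of F. There were 4 comparisons: KO against WT in cDC1, the same in cDC2, the difference of these effects between the subsets (the interaction), and WT cDC1 against WT cDC2. All changes are given as log2 fold changes unless another unit is named.

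The genes named were set by a rule before the data were examined. It takes Zfp366 and 9 regulators or cytokines of dendritic cells (Irf8, Irf4, Batf3, Id2, Nfil3, Zeb2, Bcl6, Zbtb46, Il12b). For KO against WT it adds the 8 largest rises and 8 largest falls among called genes whose KO and WT libraries do not overlap, with a mean CPM of at least 5 in the higher group. It adds up to 4 members per gene list by smallest p. For the WT subsets it takes 5 genes per direction and the members of both subset signatures, and for the interaction the 8 smallest p. Predicted genes and receptor segments were skipped.

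The 26 gene lists were also fixed before the data were examined. Cell types were covered by the cDC1 and cDC2 signatures and by markers of plasmacytoid dendritic cells, macrophages, monocytes, B cells, T cells, NK cells, neutrophils, and erythroid cells with platelets. Functions were covered by dendritic cell transcription factors, MHC class I presentation, MHC class II presentation, cross-presentation, pattern recognition receptors, cytokines and chemokines, chemokine and migration receptors, dendritic cell maturation, interferon-stimulated genes, cell cycle, immediate early and heat shock genes, mitochondrially encoded mRNAs, cholesterol biosynthesis, glycolysis, apoptosis regulators, and chromosomal neighbours of Zfp366. Lists were tested with camera and fry (limma 3.58.1), Benjamini-Hochberg adjusted over the lists. Camera was run with a preset correlation of 0.01 and with an estimated correlation. It compares a list with all other genes, whereas fry asks whether the members move, on balance, one way. Some genes stand in more than 1 list; 11 of the 28 genes of the cDC1 signature and 9 of the 24 of the cDC2 signature also belong to others. Subset-biased genes were the 100 with the largest fold change in each direction between the WT subsets, among called genes with an average log2 CPM of at least 3.

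The replicate numbers were checked before any block was used. Residual correlations between KO and WT libraries of the same number were 0.02, -0.07 and 0.11 in cDC1, and -0.05, -0.05 and -0.06 in cDC2. For 2 of the 12 libraries the best partner of the other genotype in its subset had the same number. These correlations thus gave no sign that the numbers pair the genotypes within a subset, and the fit has no block. They cannot show that pairing is absent, since libraries numbered 1 differed from those numbered 2 and 3 in 353 genes over the 4 groups. In cDC2 the pair numbered 1 also had genotype differences of opposite sign, which would lower these correlations. Mouse pools do join cDC1 and cDC2 libraries, per the labels. Same-pool residual correlations were 0.26, 0.14 and 0.14 in KO and -0.20, -0.11 and -0.07 in WT. Across genotypes, cDC1 KO with cDC2 WT of the same number gave 0.34, 0.22 and 0.08, and cDC1 WT with cDC2 KO 0.38, 0.22 and 0.30. Most of these crossed values exceed those of the labelled pools, for numbers 2 and 3 as well as 1, so the residuals do not single out the labelled pools. Residuals around a mean of 3 libraries all carry any contrast of replicate 1 with replicates 2 and 3, so the 3 numbers are not separate evidence. Blocked values are given beside the results they change. In all 4 groups replicate 1 had 3.70-fold to 178-fold less Hspa1a, Hspa1b and Dnajb1 than the mean of replicates 2 and 3, but for Hsph1 and Hsp90aa1 the fold went down to 1.26, so comparisons are also given within replicates 2 and 3 and within the pair numbered 1. No replicate repeated another of its group: the chi-square per degree of freedom between them was at least 14.5.

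Alternatives fixed before the data were examined were other size factors, no filter and a stricter filter (CPM of at least 5 in 3 libraries), edgeR's legacy fit, DESeq2 1.42.0, limma-voom, blocks by replicate number or pool, only the libraries compared, and each library left out in turn. Added after the data were seen were replicates 2 and 3 alone, both cDC2 libraries numbered 1 left out, length trends taken out as offsets, and edgeR's newer quasi-likelihood fit.

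The code was tested on simulated data with 200 changed genes. In simulated cDC1 edgeR recovered 13 of 68 genes at 2-fold, 55 of 66 at 4-fold and 63 of 66 at 8-fold, with 9 false calls among 140. In simulated cDC2 it recovered 11 of 68, 50 of 66 and 62 of 66, with 8 false calls among 131. DESeq2 made 35 false calls among 189 and 41 among 185 in the same sets, and it recovered more. In simulated cDC1 it found 28 of 68 genes at 2-fold, 60 of 66 at 4-fold and 66 of 66 at 8-fold. In simulated cDC2 it found 22 of 68, 58 of 66 and 64 of 66. Figures were drawn with matplotlib 3.10.9.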

Results

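Gene expression was measured by RNA sequencing in splenic cDC1 and cDC2 of WT mice and of mice whose label gives Zfp366-/-. Each of the 4 groups had 3 libraries, so n = 3 for every mean, and each library came from 1 mouse pool. Total counts were 17090924, 20901096 and 18775571 in cDC1 WT replicates 1, 2 and 3, and 25313827, 24121179 and 23656486 in cDC1 KO. They were 28470063, 21135759 and 11330503 in cDC2 WT, and 34886405, 36761685 and 23737888 in cDC2 KO. Levels below are mean CPM ± SD, changes are log2 fold changes with their standard error (SE), and adjusted p values are from edgeR's quasi-likelihood test.

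The first comparison asked how cDC1 differed from cDC2 in WT mice, which also checks the subset labels. The libraries labelled cDC1 were far higher in Xcr1, the chemokine receptor that marks cDC1, at 999 ± 111 against 2.00 ± 2.12 CPM. They were also higher in Clec9a, a receptor for dead cells (526 ± 61.5 against 10.8 ± 14.8 CPM), in Cd8a (996 ± 274 against 23.3 ± 33.7 CPM) and in Irf8, a transcription factor that cDC1 need (2134 ± 173 against 46.0 ± 39.6 CPM). The libraries labelled cDC2 were higher in Sirpa (663 ± 148 against 24.7 ± 4.85 CPM), in Itgam, which encodes CD11b (132 ± 36.0 against 4.47 ± 1.75 CPM), in Irf4, a transcription factor of cDC2 (280 ± 37.8 against 13.8 ± 4.28 CPM), and in Clec4a4, a lectin that marks splenic cDC2 (417 ± 96.9 against 5.41 ± 1.79 CPM).

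In all, 2846 genes differed between the WT subsets, 1389 higher in cDC1 and 1457 higher in cDC2. Among the 5 genes furthest up in cDC1, 4 had no read in any WT cDC2 library. Their levels were at least 437-fold higher for Gramd2, at least 345-fold for Clnk, an adaptor of immune receptors, at least 307-fold for Gpr33, and at least 213-fold for Cyp8b1, an enzyme of bile acid synthesis. The other was Dkk3, a secreted protein of the Dickkopf family, with 1 read in the WT cDC2 libraries together and a ratio of 4486 (95% counting interval 805 to 177199). The 5 furthest up in cDC2 were Cdhr3 (-7.35, SE 0.75), Gpr25 (-7.21, SE 1.29), the calcium channel gene Ryr3 (-6.65, SE 1.03), the succinate receptor gene Sucnr1 (-6.46, SE 0.73) and the sodium channel gene Scn3a (-6.41, SE 1.29).

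Of the 28 genes of the cDC1 signature, 27 were higher in WT cDC1, Itgae by 8.75 (SE 0.87), Cadm1 by 6.72 (SE 0.53) and Tlr3 by 5.97 (SE 0.41) among them. The exception was Batf3, which did not pass (0.45, SE 0.21, adjusted p = 0.157). Of the 24 genes of the cDC2 signature, 21 were higher in WT cDC2, with S100a4 at -6.38 (SE 0.48), Dtx1 at -6.07 (SE 0.25) and Cd209a at -5.43 (SE 0.38). Clec12a was higher in cDC1 (2.21, SE 0.25), and Notch2 (0.02, SE 0.44) and Fcrl5 (0.53, SE 1.13) did not pass. Notch2 turned to -0.92 without cDC1 WT replicate 1 and to -1.14 within replicates 2 and 3. Within replicates 2 and 3, 6391 genes passed. With the mouse pool as a block 2235 genes passed, 2125 of them among the 2846, and with only the 6 WT libraries in the fit 1537 passed. The libraries of the WT subsets did not overlap for 32.7% of all genes, where chance gives 10%. Among the signature genes, Tcf4 lost its call without cDC1 WT replicate 2 (adjusted p = 0.0620), Klf4 with the mouse pool as a block (0.0506), and Wdfy4 in 9 of its 21 alternatives, with an adjusted p of up to 0.174; outside the signatures, Gpr25 and Scn3a lost it with limma-voom (0.0664 and 0.197).

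Zfp366, Entrez Gene 238803, lies on chromosome 13 at bases 99184823 to 99247032. In cDC1 its level was 103 ± 44.0 CPM in WT (152, 89.2 and 67.5 in replicates 1, 2 and 3) and 47.5 ± 1.85 CPM in KO. It fell by 1.12 in cDC1 (SE 0.27, adjusted p = 0.0326). In cDC2 it was 57.4 ± 4.91 CPM in WT and 66.9 ± 12.9 CPM in KO (0.22, SE 0.27, adjusted p = 1). The difference between these effects did not pass (-1.34, SE 0.38, adjusted p = 0.144). Within replicates 2 and 3 the cDC1 change was -0.76 (adjusted p = 0.00163) and within the pair numbered 1 it was -1.64. The cDC1 call ended without cDC1 KO replicate 1, 2 or 3 (adjusted p = 0.114, 0.127 and 0.142), without cDC1 WT replicate 2 (0.0718) and without cDC2 KO replicate 3 (0.0562), over a range of 0.00163 to 0.142 for all alternatives. Counts are per gene, so they do not show which exons the reads in the KO libraries cover.

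The second comparison asked what differs between KO and WT cDC1. Of the 24 genes of the cDC2 signature 13 rose in the KO cDC1 libraries. Among genes typical of cDC2, Irf4 rose from 13.8 ± 4.28 to 87.0 ± 12.9 CPM (2.66, SE 0.26, adjusted p = 0.000101), Itgam from 4.47 ± 1.75 to 125 ± 4.20 CPM (4.80, SE 0.42) and Clec4a2, a C-type lectin, by 5.59. Of the 28 genes of the cDC1 signature 3 fell and 25 did not pass: Itgae, which encodes the integrin CD103, fell from 176 ± 40.1 to 10.8 ± 0.63 CPM (-4.02, SE 0.66). Outside that signature, Cd207, which encodes langerin, fell from 130 ± 77.2 to 1.72 ± 0.66 CPM (-6.24, SE 0.70). Of 27 interferon-stimulated genes 11 rose and 16 did not pass; among the risen was Oas3, which senses double-stranded RNA and went from 2.46 ± 1.02 to 151 ± 4.79 CPM (5.94, SE 0.58).

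**Figure D1:**
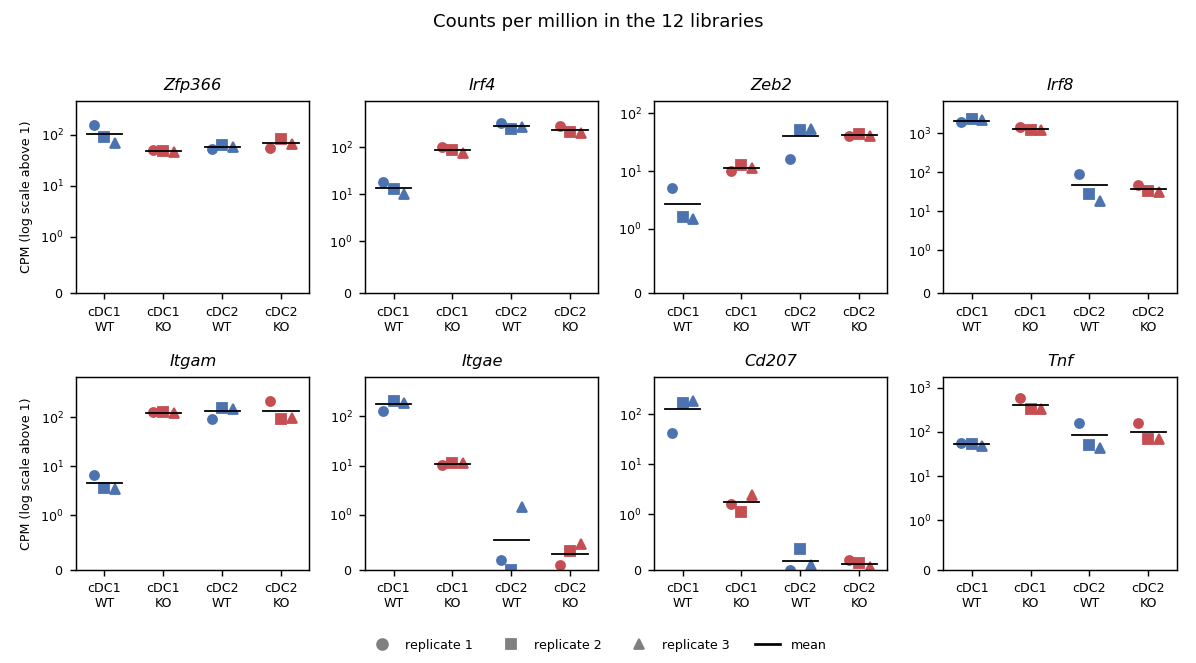
Expression in CPM (y axis, log scale above 1 and linear below) of 8 genes in the 12 libraries, grouped on the x axis by subset and genotype; symbols give the replicate and lines the mean. In cDC1 the 3 KO libraries lie above the 3 WT libraries for Irf4, Zeb2, Itgam and Tnf, and below them for Zfp366, Irf8, Itgae and Cd207.

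In cDC1, 714 genes were called between KO and WT, 483 higher and 231 lower in KO. The largest rises were Klrb1b, a lectin-like receptor of the NKR-P1 family (9.19, SE 1.49, from 0.34 ± 0.24 to 203 ± 43.6 CPM), Sv2b, a synaptic vesicle protein (9.15, SE 1.11), and Gria3, a glutamate receptor subunit (7.18, SE 0.68). Next came Il12rb1, a chain of the IL-12 receptor (6.72, SE 0.77), the lectin Clec4b1 (6.18, SE 0.74), Spon1 (6.05, SE 0.61) and Oas3. Abca6, a lipid transporter, had 3 reads in the WT cDC1 libraries together and a ratio of 114 (95% counting interval 38.8 to 550). The largest falls were Apold1 (-8.16, SE 1.71, from 255 ± 81.4 to 0.88 ± 0.23 CPM), Cnnm1 (-6.91, SE 0.82), Itm2a (-6.81, SE 0.74), Cd207, the adhesion receptor Adgrf5 (-5.69, SE 1.01), Trabd2b (-5.39, SE 0.94), Mgll, a monoacylglycerol lipase (-4.38, SE 0.77), and Lhfpl2 (-4.18, SE 0.55). Of the 9 regulators chosen in advance, Irf4 and Zeb2 (2.07, SE 0.49, adjusted p = 0.0297) rose. The rest did not pass: Irf8 (-0.71, SE 0.45, adjusted p = 0.435), Batf3 (-0.20), Id2 (0.22), Nfil3 (0.27), Bcl6 (0.77), Zbtb46 (-0.26) and the cytokine gene Il12b (-0.78). Within replicates 2 and 3, Irf8 (-0.86, adjusted p = 0.000716), Batf3 (-0.43, 0.0128), Nfil3 (0.84, 0.000306) and Bcl6 (1.16, 4.6e-05) did pass, and Il12b was 0.40 (0.0510); in the pair numbered 1 these had -0.45, 0.28, -0.51, 0.24 and -1.88.

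The count in cDC1 depended on the libraries used. Within replicates 2 and 3, 6438 genes passed. Of the 2607 of these that were at least 2-fold apart, 1431 (54.9%) had the same sign in the pair numbered 1, which took no part in choosing them, with r = 0.58. Gene length parted the genotypes in replicates 2 and 3. Spearman's correlation of gene length with a library's levels, relative to all libraries, was 0.41 and 0.32 in KO and -0.24 and -0.34 in WT. In the pair numbered 1 it was 0.30 in KO and 0.45 in WT. Length offsets were run over all 12 libraries only, with 980 calls, 676 of them among the 714. Calls within replicates 2 and 3 were thus not freed of this trend. Without cDC1 WT replicate 1 the count was 3052. It was 384, 346 and 344 without cDC1 KO replicate 1, 2 or 3, and 318 and 346 without cDC1 WT replicate 2 or 3. DESeq2 called 1291 genes. The KO and WT libraries did not overlap for 26.9% of all genes, where chance gives 10%. Zeb2 lost its call without cDC1 KO replicate 1, 2 or 3 (adjusted p = 0.0653, 0.101 and 0.0872) or cDC1 WT replicate 2 or 3 (0.145 and 0.132), over a range of 5.6e-07 to 0.145 for its alternatives. Apold1 lost it without cDC1 KO replicate 1, 2 or 3 (0.0796, 0.0841 and 0.0754), over a range of 1.8e-09 to 0.0851. Adgrf5 lost it without cDC1 KO replicate 3 (0.0595), and Trabd2b without cDC1 KO replicate 2 or cDC1 WT replicate 2 (up to 0.0747).

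By the lists fixed in advance, the clearest group change in KO cDC1 was the cDC2 signature: 13 of its 24 genes rose, none fell and 11 did not pass, and adjusted over the list alone 19 rose. Dtx1, a target of Notch signalling, rose from 2.48 ± 0.38 to 39.0 ± 5.60 CPM (3.97, SE 0.23, adjusted p = 4.9e-06), Clec4a4 by 3.77 (SE 0.35), Sirpa by 2.05 and Clec10a by 4.21. Clec4a4, Clec4a2 and Cd4, which also rose, lie in a region of chromosome 6 that held more calls than the rest of the genome, as described below. Camera called the list (adjusted p = 4.7e-16, and 0.000337 with an estimated correlation). Of the 28 genes of the cDC1 signature 3 fell, none rose and 25 did not pass; adjusted over the list alone 4 fell. The 3 were Itgae, the lipid phosphatase gene Plpp1 (-2.33, SE 0.34) and Ppt1, a lysosomal thioesterase (-1.27, SE 0.25), whose adjusted p rose to up to 0.0627 without cDC1 KO replicate 2 or 3 or cDC1 WT replicate 2. Camera called this list lower (adjusted p = 0.000179, and adjusted p = 0.274 with an estimated correlation).

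Interferon-stimulated genes formed the next group, with 11 of 27 risen, none fallen and 16 not passed; adjusted over the list alone 20 rose and 1 fell. Gbp2, a guanylate-binding protein, rose from 26.2 ± 1.14 to 126 ± 7.50 CPM (2.27, SE 0.20), Oasl2 by 4.49 (SE 0.49) and Oas1a by 2.74 (SE 0.34). Camera gave an adjusted p of 1.3e-13, and adjusted p = 0.119 with an estimated correlation. Of 23 pattern recognition receptors 7 rose and none fell, 7 also when adjusted over the list alone, with Tlr1 (2.26, SE 0.22), Ddx58, which encodes the RNA sensor RIG-I (3.17, SE 0.40), the beta-glucan receptor gene Clec7a (3.10, SE 0.47) and Sting1 (2.03, SE 0.32). Camera called these receptors higher (adjusted p = 0.000229, and adjusted p = 0.271 with an estimated correlation). Of 26 cytokines and chemokines 6 rose and none fell, and adjusted over the list alone 11 rose and 3 fell; Ccl9 rose from 3.93 ± 0.66 to 147 ± 10.2 CPM (5.22, SE 0.50), Ccl6 by 2.38 (SE 0.30) and Tnf from 52.7 ± 3.84 to 409 ± 137 CPM (2.95, SE 0.51). This list was called by camera (adjusted p = 0.00105, and 0.0326 with an estimated correlation).

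Of the 22 immediate early and heat shock genes 3 rose and none fell, 6 and 0 when adjusted over the list alone; all 3, Egr1 (2.50, SE 0.28), Ier2 (1.46, SE 0.22) and Zfp36 (1.58, SE 0.24), are immediate early genes (camera adjusted p = 1.2e-05, and 0.0326 with an estimated correlation). Among 30 dendritic cell transcription factors Irf4 and Zeb2 alone rose, and 7 rose when adjusted over the list alone (camera adjusted p = 0.00471, and adjusted p = 0.464 with an estimated correlation). No MHC class I presentation gene of 19 passed, though 3 were lower when adjusted over the list alone and camera called the list lower (adjusted p = 0.00841, and adjusted p = 0.645 with an estimated correlation). No mitochondrially encoded mRNA of 13 passed, also not when adjusted over the list alone; camera called them lower (adjusted p = 0.0199, and adjusted p = 0.864 with an estimated correlation). That call ended without cDC1 WT replicate 1 (adjusted p = 0.603) and without cDC1 KO replicate 2 or 3 (0.114 and 0.391). Camera thus called 9 lists, of which the cDC2 signature, cytokines and chemokines, and immediate early and heat shock genes kept their call with an estimated correlation. By fry 8 lists were called, cross-presentation among them (higher, fry adjusted p = 0.0301). MHC class I presentation and mitochondrially encoded mRNAs were not (fry adjusted p = 0.135 and 0.501).

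Camera called none of the other lists in cDC1. Of 23 cross-presentation genes 3 rose and 1 fell, 4 and 2 when adjusted over the list alone; Cybb, part of the NADPH oxidase, rose from 16.5 ± 1.88 to 195 ± 1.10 CPM (3.57, SE 0.28). Of 18 chemokine and migration receptors 4 rose and 1 fell, 7 and 2 over the list alone, with Gpr183, an oxysterol receptor, up by 3.05 (SE 0.42). Of 25 dendritic cell maturation genes 3 rose and none fell, 3 and 1 over the list alone, with Marcksl1 up by 1.31 (SE 0.23). Of 14 MHC class II presentation genes Lgmn rose (1.23, SE 0.17), as it did over the list alone. Of 21 apoptosis regulators Bmf rose (1.24, SE 0.26) and Fas, a death receptor, fell (-1.94, SE 0.36), 3 and 2 over the list alone; Bmf had an adjusted p of up to 0.0855 without cDC1 KO replicate 1 or cDC1 WT replicate 2 or 3. None of 26 cell cycle, 21 cholesterol biosynthesis or 17 glycolysis genes passed, nor did any of the 12 measured chromosomal neighbours of Zfp366, and none did over the list alone.

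Markers of other cell types went in both directions in KO cDC1. Of 16 plasmacytoid dendritic cell markers 1 rose and 2 fell (3 and 2 adjusted over the list alone), and Lair1, an inhibitory receptor, was the riser (2.03, SE 0.22). Of 18 macrophage markers Cd163 rose (4.24, SE 0.45) and 2 fell, 3 and 2 over the list alone. Of 14 monocyte markers 3 rose and 1 fell, as over the list alone, with Ms4a4c up by 2.23 (SE 0.21). Of 12 B cell markers Fcrla rose (2.81, SE 0.53), as over the list alone; of 7 T cell markers Cd8b1 rose (4.37, SE 0.80), and over the list alone 1 rose and 1 fell. None of 7 NK cell, 9 neutrophil, or 7 erythroid and platelet markers passed, also not over the list alone. Medians and means differed in sign for the NK cell, neutrophil, MHC class II, cross-presentation and neighbour lists, and fry's direction differed from camera's for the macrophage and B cell lists. Within replicates 2 and 3 the cDC2 signature had 21 genes higher and 1 lower, the cDC1 signature 2 and 15, and interferon-stimulated genes 24 and 1. Pattern recognition receptors had 10 and 5, cytokines 12 and 4, transcription factors 18 and 4, and immediate early and heat shock genes 19 and 0. MHC class I genes had 1 and 11, and mitochondrial mRNAs 0 and 11. Plasmacytoid dendritic cell markers had 8 and 2, macrophage markers 5 and 7, monocyte markers 5 and 3, and erythroid and platelet markers 1 and 4. In that fit 3349 of all 13461 genes were higher and 3089 lower, so counts near these shares say little of a list. Gene length also parted the genotypes there.

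Genes that separate the WT subsets were followed in KO cDC1. Of the 100 genes most biased to WT cDC2, 69 rose, none fell and 31 did not pass, with a median of 2.36. Of the 100 most biased to WT cDC1, 3 rose, 16 fell and 81 did not pass, with a median of -0.64. Both lists come from the same WT cDC1 libraries that serve as control, so these counts are not independent evidence; 10 simulations of that sharing alone gave mean medians of 0.06 and -0.06. Chosen from the KO libraries instead, the cDC2-biased list had 32 risen, 4 fallen and a median of 0.97, and the cDC1-biased list 11 risen, 7 fallen and a median of -0.08. With an estimated correlation, the unadjusted camera p was 0.000286 for the WT cDC2 list and 0.00777 for the WT cDC1 list. Of the 483 genes that rose in KO cDC1, 367 were higher in WT cDC2 and 9 in WT cDC1, and of the 231 that fell, 138 were higher in WT cDC1 and 7 in WT cDC2. Of all genes higher in WT cDC2, 82.4% had a positive change in KO cDC1, and of all genes higher in WT cDC1, 74.7% had a negative one. The same simulations gave means of 59.6% (highest 61.4%) and 60.2% (highest 61.9%). They drew each gene independently, so they leave out shifts that many genes share within a WT cDC1 library. Their spread is therefore too narrow to exclude the shared control as a source.

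**Figure D2:**
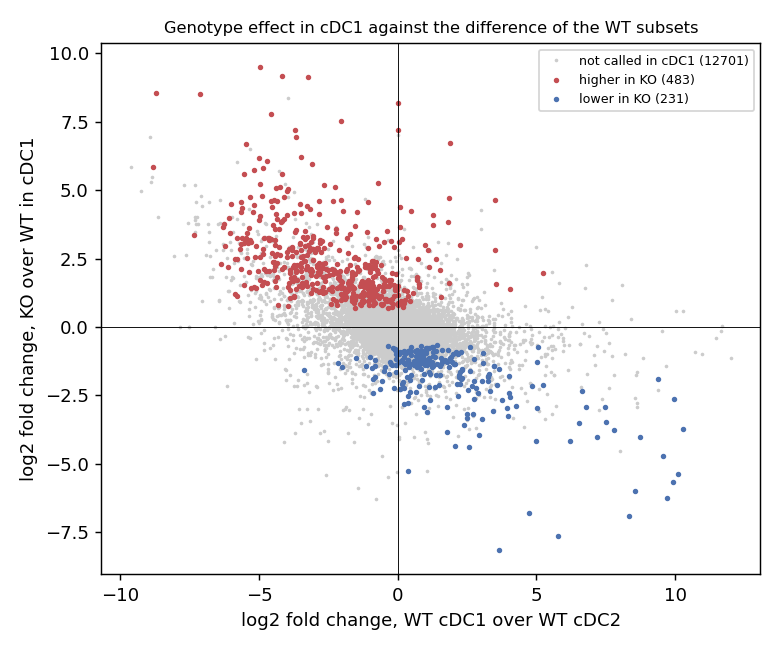
Each point is 1 of the 13415 genes tested, with the log2 fold change of WT cDC1 over WT cDC2 on the x axis and of KO over WT in cDC1 on the y axis; the 483 genes called higher and the 231 called lower in KO are coloured. Of the higher genes, 367 were also called higher in WT cDC2, and of the lower genes 138 were called higher in WT cDC1; both axes share the WT cDC1 libraries.

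The third comparison asked what differs between KO and WT cDC2, where no marker of the subset passed the test. Irf4 was 280 ± 37.8 CPM in WT and 232 ± 43.1 CPM in KO (-0.27, SE 0.24), Zeb2 40.6 ± 21.0 and 41.8 ± 1.93 CPM (0.04, SE 0.45), and Dtx1 167 ± 24.1 and 206 ± 20.4 CPM (0.31, SE 0.20). Irf8 (-0.32, SE 0.45), Batf3 (-0.07, SE 0.21), Id2 (-0.20), Nfil3 (-0.28), Bcl6 (0.26), Zbtb46 (-0.25) and Il12b (-0.08) did not pass either. Several of these average opposite signs: within replicates 2 and 3 and in the pair numbered 1, Irf8 was 0.45 and -0.98, Id2 0.27 and -1.51, Zeb2 -0.32 and 1.30, Bcl6 -0.02 and 0.70, Il12b -0.31 and 0.82, and Nfil3, which passed in replicates 2 and 3 (adjusted p = 0.00242), -0.85 and 0.65. Over all 6 libraries edgeR called 0 genes in cDC2 (smallest adjusted p = 1), as did DESeq2 and limma-voom (0 each), with 271 genes at an unadjusted p under 0.05. In 5.88% of genes KO and WT cDC2 did not overlap, where chance gives 10%. None of the 26 lists had a member that passed, over all genes or adjusted over the list alone. Camera called interferon-stimulated genes lower (adjusted p = 0.000115), as in Oasl1 (-1.27, SE 0.44, adjusted p = 1) and Irgm1 (-0.62, SE 0.27, adjusted p = 1), MHC class I presentation lower (adjusted p = 0.0103) and mitochondrially encoded mRNAs higher (adjusted p = 0.000115). Each of these had adjusted p = 0.877 with an estimated correlation, and fry called none. The interferon call ended without cDC2 WT replicate 2 (0.292), the mitochondrial call without cDC2 WT replicate 1 (0.0699), and the class I call without cDC2 WT replicate 1 or 2 (0.105 and 0.152) or cDC2 KO replicate 2 or 3 (0.430 and 0.238).

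The cDC2 result depended on the libraries numbered 1. Within replicates 2 and 3, 1039 genes passed, 451 higher and 588 lower in KO. There 19 of 27 interferon-stimulated genes were lower and 1 higher, such as Zbp1, a nucleic acid sensor (-1.47, SE 0.13, adjusted p = 5.9e-05), Rtp4 (-1.39, SE 0.16) and Oasl1 (-1.88, SE 0.32), while in the pair numbered 1 the same genes had 1.15, 0.58 and 0.48. MHC class I genes had 8 lower and none higher of 19, monocyte markers 5 lower and none higher of 14, and cytokines 7 lower and 3 higher of 26. Among the genes furthest apart, chosen after their values were seen, were Klra3, a lectin-like receptor (10.61, and -5.73 in the pair numbered 1), Gal, which encodes galanin (9.06 and -7.36) and St8sia3 (7.77 and -7.14), all higher, and Sectm1a (-6.95 and 3.71), Erdr1 (-6.11 and 4.87) and Hebp1 (-4.91 and 4.45), all lower. With both cDC2 libraries numbered 1 left out, 122 genes passed. Leaving out any single library gave 0, with 11 lists called by camera without cDC2 KO replicate 1 and 6 without cDC2 WT replicate 3.

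**Figure D3:**
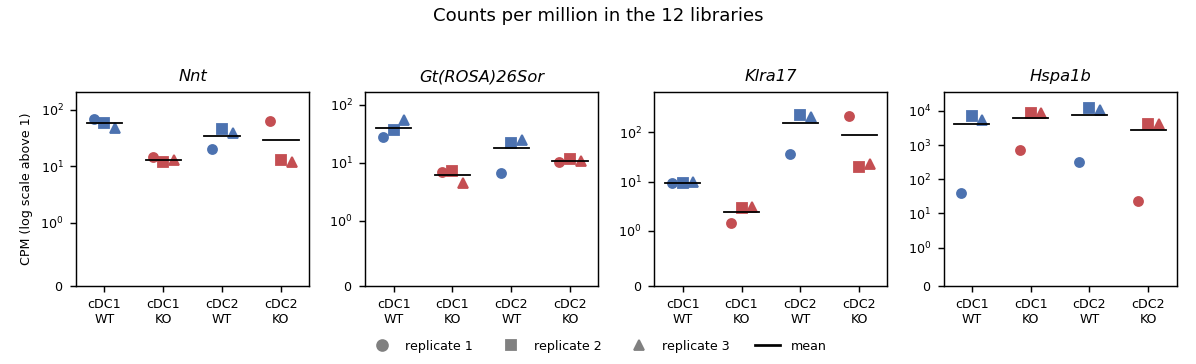
Expression in CPM (y axis, log scale above 1) of Nnt, Gt(ROSA)26Sor, Klra17 and Hspa1b in the 12 libraries, grouped by subset and genotype; symbols give the replicate and lines the mean. In cDC2 replicate 1, Nnt was 19.8 in WT and 62.3 in KO, whereas replicates 2 and 3 had 46.0 and 37.8 in WT and 12.7 and 11.96 in KO; Hspa1b was lowest in replicate 1 of all 4 groups.

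In the subset-biased genes, no member passed in cDC2. The 100 genes most biased to WT cDC1 had a median of -0.16 (p = 0.0493 by camera, 0.358 with an estimated correlation) and the 100 most biased to WT cDC2 a median of 0.20 (p = 0.0156, and 0.296 with an estimated correlation). The first turned to 0.41 without cDC2 WT replicate 1 and to 0.14 within replicates 2 and 3. The second was 0.072 without cDC2 WT replicate 2, 0.087 without cDC2 WT replicate 1 and 0.12 without cDC2 WT replicate 3.

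The fourth comparison asked whether the genotype effect differed between the subsets. The genes named by smallest p had larger effects in cDC1. Dtx1 had a difference of 3.66 (SE 0.30), Skint3 5.50 (SE 0.47) and the receptor gene Cd72 3.87 (SE 0.33), each with an adjusted p of 0.000185. Mmp12, an elastase of macrophages (2.78, SE 0.28), Fcer1g, the shared signalling chain of Fc receptors (3.72, SE 0.40), the phosphatase gene Ptpro (3.58, SE 0.38), Gbp2 (2.46, SE 0.27) and Cybb (3.33, SE 0.37) had 0.000842. In cDC1 Skint3 went from 9.17 ± 3.06 to 439 ± 43.5 CPM and Fcer1g from 28.1 ± 5.90 to 405 ± 27.4 CPM, against 165 ± 48.4 and 176 ± 59.3 CPM for Skint3 and 519 ± 132 and 566 ± 168 CPM for Fcer1g in WT and KO cDC2.

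In all, 190 genes had an effect that differed, 170 in the positive and 20 in the negative direction, and 189 of these were called in cDC1 with the same sign. The cDC2 effect in this difference averages opposite signs for some genes. This was seen in 179 genes at least 2-fold apart the same way in replicates 2 and 3 of both subsets. Their median cDC2 change along that sign was 1.93 there and -1.45 in the pair numbered 1. Of 100 splits of the genotype labels 9 kept the cDC1 labels, the real one included, and 8 of these gave at least 190 genes. Of the 24 cDC2 signature genes 9 had the larger effect in cDC1 and none the smaller, 14 and 0 adjusted over the list alone, with Clec4a2 at 5.19 and Itgam at 4.76. Of 27 interferon-stimulated genes 7 did (18 over the list alone), with Oas3 at 5.30 and Oasl2 at 4.91, and of 26 cytokines and chemokines 2 (7 over the list alone), Ccl9 at 4.95 and Ccl6 at 2.40. Immediate early and heat shock genes had 2 of 22 (4 over the list alone), Egr1 at 2.39 and Ier2 at 1.51. Camera called 9 lists. These 4 kept their call with an estimated correlation (adjusted p = 0.000153, 0.0368, 0.00643 and 0.0167). The others did not: pattern recognition receptors higher with 3 of 23 members (adjusted p = 6.9e-07, and adjusted p = 0.0874 with an estimated correlation), transcription factors higher with Irf4 (0.00583, and adjusted p = 0.402 with an estimated correlation), chemokine and migration receptors higher with Gpr183 (0.00322, and adjusted p = 0.364 with an estimated correlation), the cDC1 signature lower with no member (0.0243, and adjusted p = 0.466 with an estimated correlation) and mitochondrial mRNAs lower with no member (1.0e-05, and adjusted p = 0.402 with an estimated correlation). The cDC1 signature lost its call without cDC2 WT replicate 2 or 3 (0.319 and 0.0892), cDC1 WT replicate 1 (0.0516) or cDC2 KO replicate 1 (0.0738), and the chemokine receptors without cDC2 WT replicate 1 (0.0961). With the mouse pool as a block 116 genes passed, 101 of them among the 190, and within replicates 2 and 3, 5157 passed. The count was 118, 114 and 111 without cDC1 KO replicate 1, 2 or 3, 118 without cDC2 KO replicate 2 or 3, 110 without cDC1 WT replicate 2 and 501 without cDC1 WT replicate 1.

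Across the 13415 genes, the genotype effects in cDC1 and cDC2 correlated weakly, with Pearson's r of 0.16 (jackknife SE 0.14 over the libraries) and Spearman's rho of 0.21. Genes are not independent replicates, so no p is given. In the 714 genes called in cDC1 r was 0.14 and rho 0.19, which averages opposite signs: with the cDC2 pairs numbered 1, 2 and 3 taken singly r was -0.30, 0.35 and 0.32.

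Called genes were also placed along the chromosomes. Within 25 Mb of Gt(ROSA)26Sor on chromosome 6, 37 of 278 genes were called in cDC1 (13.3%), against 5.25% elsewhere, and within 20 Mb of Zfp366 9 of 135 were (6.67%). In the chromosome 6 region Klrb1b, Clec4b1, Clec4a2 and Cd163 rose, and Apold1, Mgll and Gt(ROSA)26Sor itself (-2.67, SE 0.44, adjusted p = 0.00309) fell; the centre of the region was chosen after the values were seen.

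**Figure D4:**
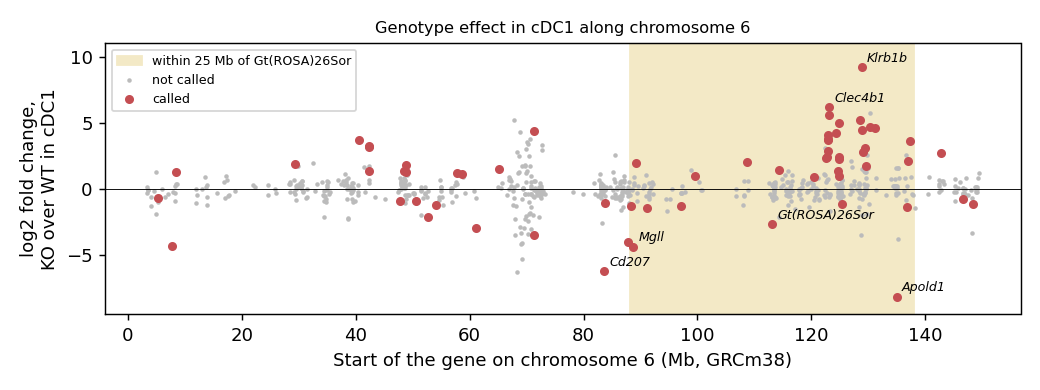
Log2 fold change of KO over WT in cDC1 (y axis) for the tested genes of chromosome 6 by the start of the gene in Mb on GRCm38 (x axis); called genes are red and the shaded band lies within 25 Mb of Gt(ROSA)26Sor. In the band 37 of 278 genes were called.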

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

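Chosen only after the result was seen were the tests for cDC2 cells in the cDC1 sort, exchanged labels, the additive replicate term, DNA around Gt(ROSA)26Sor, the calls around Zfp366 in cDC2, reads shared between paralogs there, the share of cDC2-type genes near Zfp366 or Gt(ROSA)26Sor, and the splits of the cDC1 and of the cDC2 libraries; the other tests were set beforehand.

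By edgeR's test of the difference itself, the genotype effect differed between cDC1 and cDC2 for 190 genes and, by camera, for 9 gene lists, 4 of which kept the call with an estimated correlation. The named genes, all with the larger effect in cDC1, were Dtx1 (3.66), Skint3 (5.50), Cd72 (3.87), Mmp12 (2.78), Fcer1g (3.72), Ptpro (3.58), Gbp2 (2.46) and Cybb (3.33). Of the 190 genes, 143 were higher in WT cDC2 than in WT cDC1. Exchanging genotype labels within each subset gave at least 190 genes in 8 of 100 splits (the real one included, out of 200 possible), with a highest other count of 790, so chance is not excluded by this count. That split exchanges the cDC2 libraries numbered 2 and 3, and the one that exchanges those numbered 1 gave 411; both part the cDC2 libraries the same way, with the opposite sign of the cDC2 effect, which points to a structure of these samples. All 8 kept the cDC1 labels, and the highest count with mixed cDC1 labels was 8.

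The first pattern was the rise of cDC2-type genes in KO cDC1, 367 of the 483 risen genes. Against an admixture of cDC2 cells stands the share of such cells that each of 99 strongly cDC2-specific genes would need: 2.48% at the 10th and 67.2% at the 90th percentile, a 27.2-fold range where 1 admixture needs about 1 share. The 10 most abundant of them needed a median of 9.81% (2.46% to 73.2%), so 1 admixture of average cDC2 could not be the whole source. How large a part it could be is not bounded, since 30 of the 99 genes needed under 5%. An admixture of cells unlike the average cDC2 was not tested, and the sort gates are not given in the sources used here. Of the risen cDC2-type genes 94.6% kept their call with length trends taken out, which argues against length bias as the whole source. Within 20 Mb of Zfp366 or Gt(ROSA)26Sor lay 7.08%, which argues against linked DNA that acts on nearby genes as the whole source. Few genes lie there at all: of 13031 with a position, 135 within 20 Mb of Zfp366 and 278 within 25 Mb of Gt(ROSA)26Sor. A high share was therefore unlikely from the start. The 7.08% is above the share of all genes, so linked DNA as a part of the source is not excluded. Linked DNA that acts on genes elsewhere was not tested. That cDC1 of mice labelled Zfp366-/- take on part of the cDC2 programme stays a hypothesis, found and tested on the same libraries; Zfp366 reads there fell by 1.12 and remained, so a loss of its function is not shown, and the 10 splits of 3 against 3 are too few for a share under 0.05 (714 genes in the real split, 0 in the highest other).

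The second pattern was the absence of called genes in cDC2 over all 6 libraries, against 1039 within replicates 2 and 3. An additive term for the replicate number gave 0 genes and taking out length trends gave 0, so neither a shift shared by the libraries numbered 1 nor gene length accounts for it. Among the genes at least 2-fold apart in replicates 2 and 3, 8.79% (42 of 478, r = -0.80) had the same sign in the cDC2 pair numbered 1, against 54.9% (1431 of 2607, r = 0.58) in cDC1. The cDC1 pair is thus a weak yardstick for genes chosen in 1 subset. For the 179 genes at least 2-fold apart the same way in replicates 2 and 3 of both subsets, 87.2% (156) had the same sign in the cDC1 pair numbered 1 but 7.26% (13) in the cDC2 pair, with r of 0.80 and -0.84. Their median change along that sign was 1.93 in cDC2 replicates 2 and 3 and -1.45 in the cDC2 pair numbered 1. Exchanged labels of the cDC2 libraries numbered 1 are therefore a candidate explanation, found and tested on the same libraries, and the labels were kept as given, so the cDC2, interaction, WT subset and subset-biased values over all libraries, and the overlaps of cDC1 genes with them, include this pair as labelled. The 714 genes called in cDC1 had r of -0.30, 0.35 and 0.32 with the cDC2 pairs numbered 1, 2 and 3. For the 37 of them near Gt(ROSA)26Sor these were -0.70, 0.63 and 0.67. Libraries labelled as 1 pool also differed in Nnt, a gene picked after its values were seen. It was 14.4 CPM in cDC1 and 62.3 CPM in cDC2 of KO replicate 1. In WT replicate 1 it was 68.3 CPM in cDC1 and 19.8 CPM in cDC2. The 10 splits are too few for a share under 0.05, and of them the one that exchanges the cDC2 libraries numbered 1 gave 238 genes, the real one 0, which points to a structure of these samples.

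The third pattern was that genes called in cDC1 lie close together on the chromosomes. Within 25 Mb of Gt(ROSA)26Sor the odds ratio of a call was 2.77 (95% interval 1.89 to 3.97, which, as do the others here, takes genes as independent), and without genes of neighbouring families 2.16 (1.33 to 3.37), and in cDC2 replicates 2 and 3 it was 2.31 (1.63 to 3.22). The region was chosen after values of both subsets were seen, so these odds ratios do not test it independently. The excess was not centred on Gt(ROSA)26Sor. Bases 110000001 to 120000000, which hold it, had 2 called genes of 67, and bases 120000001 to 130000000 had 22 of 123. DNA of another strain in this region is a candidate explanation that cannot be told apart from joint regulation of neighbouring genes, which was not tested. With no region chosen, 84 pairs of neighbouring genes were both called, against a mean of 38.5 (highest 58) in 1000 shuffles of the calls. Without gene families these were 48 against 27.9 (highest 46), so reads shared between paralogs of 1 name stem do not account for all of the clustering, though families make up part of it. Within 20 Mb of Zfp366 the odds ratio was 1.25 (0.556 to 2.46); an interval that includes 1 had been set beforehand to exclude strain DNA there, but this one also covers 2.16. In cDC2 replicates 2 and 3 it was 0.727 (0.306 to 1.48, with 8 of 135 genes called). That interval lies below 2.16 but covers 1 and the 1.25 of cDC1, so it cannot decide. Other values go with strain DNA there, so it stays open. On chromosome 13, bases 110000001 to 120000000, which the window covers in part, held 6 called genes of 33 (Fisher's exact test over the genes, p = 0.00782, adjusted p = 0.236). Nnt, called lower in KO cDC1 (-2.15), lies just outside the window. Of 211 bins of 10 Mb, 2 held more calls than others after adjustment, on chromosome 6 at bases 120000001 to 130000000 (22 of 123 genes) and on chromosome 1 at bases 170000001 to 180000000 (18 of 95, Fcgr2b, Fcrla and Fcer1g among them).

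For the WT subsets the 10 splits are likewise too few for a share under 0.05; the real split gave 2846 genes and the highest other 879. That other split exchanges the cDC1 and cDC2 libraries numbered 1.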

How the results depend on the processing

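Replicates 2 and 3 alone, leaving out both cDC2 libraries numbered 1, length offsets and the newer quasi-likelihood fit were chosen after seeing the data; the other alternatives were planned, and edgeR's legacy fit is the fit used here, so it changed nothing. The correlation of the genotype effects, the Zfp366 level in cDC2 and the medians of the subset-biased genes in cDC1 kept their direction and side of the threshold, or moved by less than their spread, under all alternatives run. Of 5420 planned values of the 303 named gene results, 5202 kept call and direction, 106 lost and 76 gained a call, 35 uncalled ones changed sign and 1 reversed; of 909 added values these were 768, 2, 111, 27 and 1. Of 348 planned values of the 21 called lists 319 kept their call and 29 lost it, and of 42 added ones 41 and 1. Calls in cDC1 numbered 1291 with DESeq2 and 6438 with replicates 2 and 3 alone. They numbered 1206 with both cDC2 libraries numbered 1 left out, and 318 to 3052 with 1 library left out. In simulated data DESeq2 made more false calls than edgeR and also recovered more of the changed genes. Blocking by replicate number gave 733 calls in cDC1, 616 of them among the 714, and 0 in cDC2. Calls in cDC2 numbered 1039 with replicates 2 and 3 alone and 122 with both cDC2 libraries numbered 1 left out. Genes whose effect differs between the subsets numbered 302 with length offsets, 116 with the pool block, 459 with DESeq2, 5157 with replicates 2 and 3 alone, 336 with both cDC2 libraries numbered 1 left out, and 110 to 501 with 1 library left out. WT subsets gave 1537 with only their 6 libraries, which leaves fewer libraries for the spread, and 6391 with replicates 2 and 3 alone. The Zfp366 change in cDC1 ranged from -1.35 to -0.72 with 1 library left out and lost its call in 5 of these. Notch2 between the WT subsets reversed to -0.92 without cDC1 WT replicate 1 and to -1.14 with replicates 2 and 3 alone, and was at most 0.36 with another library left out. Lists called with an estimated correlation numbered 3 in cDC1, 0 in cDC2 and 4 for the interaction. In cDC2, lists numbered 6 with the stricter filter, 8 with replicates 2 and 3 alone, 5 with both cDC2 libraries numbered 1 left out, and 2 to 11 with 1 library left out. In cDC2 the median of the WT cDC1 genes lost its call with no filter (-0.15), the stricter filter (-0.18) and an estimated correlation (-0.16), and reversed with replicates 2 and 3 alone (0.14) and with both cDC2 libraries numbered 1 left out (0.15), over -0.39 to 0.41 with 1 library left out; that of the WT cDC2 genes lost it with an estimated correlation (0.20) and with both libraries left out (0.088), over 0.072 to 0.26. Other than where named, the cause was not tested. The lowest total, 11330503 in cDC2 WT replicate 3, comes with the fewest genes detected, 12750, so depth limits low counts most in that library.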

Other observations

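All comparisons in this part were chosen only after the results above were seen; the gene lists were fixed beforehand. KO cDC1 and KO cDC2 still differed in 2264 genes, 1133 higher in cDC1 and 1131 higher in cDC2, and 1500 of the 2846 genes that separate the WT subsets also did so in KO, in the same direction. These counts and the levels below include the cDC2 libraries numbered 1 as labelled. The 367 genes that rose in KO cDC1 and were higher in WT cDC2 reached a median of 68.2% of their WT cDC2 level (quartiles 35.2% and 108%). Of these, 105 were at or above that level and 133 were still lower in KO cDC1 than in KO cDC2. The 367 were chosen for having risen. For the 99 strongly cDC2-specific genes, not chosen so, the change was a median of 11.1% of the gap between WT cDC1 and cDC2 (quartiles 4.50% and 23.6%). The 138 genes that fell and were higher in WT cDC1 kept a median of 33.1% of their WT level, and 45 of them were still higher in KO cDC1 than in KO cDC2.

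For some genes changed in KO cDC1 no difference between the WT subsets was found, which with n = 3 does not show that there is none. Of the 483 risen genes, 76 did not differ between WT cDC1 and WT cDC2 at an unadjusted p of 0.05, and of the 231 fallen genes 62 did not. Among the risen ones, the Fc receptor gene Fcgr2b went from 56.3 ± 2.82 to 323 ± 12.1 CPM (2.52, SE 0.27), the chemokine receptor gene Ccr2 from 69.4 ± 38.9 to 525 ± 87.1 CPM (2.92, SE 0.63), Tgfbi from 343 ± 31.8 to 900 ± 21.3 CPM (1.39, SE 0.20) and Atf6, a sensor of endoplasmic reticulum stress, from 114 ± 38.9 to 327 ± 21.4 CPM (1.52, SE 0.25). Among the fallen ones were Hfe, a regulator of iron uptake (-1.63, SE 0.37), Tspan3 (-0.91, SE 0.17) and Cd52 (-1.21, SE 0.32). Genes higher in WT cDC1 that rose further in KO cDC1 numbered 9, among them the serpin gene Serpinb10 (68.3 ± 2.43 to 546 ± 42.5 CPM; 3.00, SE 0.30), the leukotriene receptor gene Cysltr1 (2.08, SE 0.31), the phosphodiesterase gene Pde1b (1.39, SE 0.36) and Myb, a transcription factor of progenitors (1.60, SE 0.35). The Ccr2 call ended without cDC1 KO replicate 1 or cDC1 WT replicate 2 or 3, with an adjusted p of up to 0.0994 over a range of 1.3e-07 to 0.0994.

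Replicate 1 of every group stood apart in some heat shock and red cell transcripts. Hspa1b, an inducible heat shock gene, was 40.9, 7108 and 5442 CPM in cDC1 WT replicates 1, 2 and 3, and 743, 8581 and 8854 CPM in cDC1 KO. It was 318, 11975 and 10354 CPM in cDC2 WT, and 23.4, 4187 and 4132 CPM in cDC2 KO. Libraries numbered 1 differed from those numbered 2 and 3 in 353 genes over the 4 groups, 213 higher and 140 lower. Lower were Hspa1a (-5.49, SE 0.62), Dnajb1 (-2.95, SE 0.27), the haemoglobin gene Hba-a1 (-2.62, SE 0.21) and the macrophage gene Cd5l (-1.99, SE 0.18), and higher was the cell cycle inhibitor gene Cdkn1a (1.29, SE 0.11). By camera, macrophage, neutrophil, and erythroid and platelet markers were lower in the libraries numbered 1 (adjusted p = 8.3e-08, 5.7e-05 and 1.4e-07, and adjusted p = 0.171, 0.0862 and 0.0503 with an estimated correlation). Cholesterol biosynthesis genes were higher (adjusted p = 1.6e-06, and 0.0190 with an estimated correlation). So were mitochondrially encoded mRNAs, chemokine and migration receptors, and glycolysis genes (adjusted p = 0.00140, 0.0142 and 0.0158, and adjusted p = 0.521, 0.436 and 0.436 with an estimated correlation).

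Nnt, a mitochondrial transhydrogenase gene that carries a deletion in the C57BL/6J substrain, lies on chromosome 13 at bases 119335527 to 119409257. It was 68.3, 58.6 and 47.5 CPM in cDC1 WT replicates 1, 2 and 3 and 14.4, 11.96 and 12.9 CPM in cDC1 KO (-2.15, SE 0.56, adjusted p = 0.0434). In cDC2 it was 19.8, 46.0 and 37.8 CPM in WT and 62.3, 12.7 and 11.96 CPM in KO. Klra17, a lectin-like receptor gene of chromosome 6, was 35.9, 219 and 207 CPM in cDC2 WT and 216, 19.8 and 22.4 CPM in cDC2 KO.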
